A study of Mus musculus with 8 samples.

How the data were processed

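The series holds 8 arrays of mouse spermatogonial stem cells, and total RNA was extracted with Trizol, turned into biotin-labelled cRNA and hybridised to Affymetrix arrays, per the labels' protocols. The deposited values are RMA signals on a log2 scale, 1 per probe set and array, made with Partek 6.4 and RMA per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of a probe set. The settings used by the submitters, and any probe filter, are not given in the sources used here. The scale was read from the values, which run from 2.16 to 14.81 with array medians between 6.90 and 6.98. RMA gives no detection call, so a low value can be background. The median of all probe sets over the arrays, 6.94, served as a mark of dim signals. Scanner files, scan dates and GC content were not analysed here.

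The table has 35557 rows. Of these, 6613 have identifiers in a run before the first probe set with a gene name; they were taken to be control probe sets, an inference from the numbering, and left out. Of the 28944 probe sets tested, 21789 have 1 gene symbol in the platform annotation, 1621 have several and 5534 have none. Genes were named only through probe sets with 1 symbol, with symbols and chromosomes looked up by gene number in a RefSeq table of assembly GRCm38.p6, in which 21698 of them were found. No coordinates are given, since the build behind the array annotation is not given in the sources used here. A gene was represented by its probe set with the highest mean over the 8 arrays, which gave 19939 genes, of which 998 have more than 1 such probe set. Cdkn1a and H19, which were to be named in every comparison, are not analysed here, because no probe set carries their symbol alone.

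Samples were grouped by donor and culture time from the labels: young donor, short culture (n = 3), young donor, long culture (n = 3), and serial transplant, long culture (n = 2). The labels do not say whether replicates come from separate donors or cultures, so p-values measure only the spread between these arrays, which may be technical. No 2 arrays held identical values. All 3 pairs of groups were compared with limma 3.58.1 in R 4.3.3 (lmFit with 1 coefficient per group over all 8 arrays, contrasts and eBayes, 5 residual and 6.28 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets at 0.05 and no fold requirement. Errors of fold changes are standard errors from limma and errors of group means are SD. Whether the result depends on the intensity trend, array weights, the arrays in the fit, a filter on dim probe sets, quantile normalization or centring of the deposited values, a log2 change of at least 1, the replicate number as a block, each array left out in turn, or the mean of all probe sets of a gene was tried, and all of these were fixed before the data were examined, except that centring was added for the gene lists after seeing the data.

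A set of 33 gene lists was fixed before the data were examined: undifferentiated spermatogonia, GDNF and FGF signalling, differentiating spermatogonia, meiosis, spermatids, core germ cell genes, pluripotency, fibroblasts, Sertoli cells, Leydig cells, macrophages, endothelium, senescence-associated genes, p53 targets, oxidative stress defence, JNK and AP-1 signalling, paternally and maternally expressed imprinted genes, DNA methylation, chromatin silencing, glycolysis, oxidative phosphorylation, cholesterol synthesis, G2 and M phases, DNA replication, DNA repair, telomeres, interferon response, Bcl2 and caspase families, unfolded protein response, heat shock, Y-linked genes, and integrins and niche adhesion. Each was tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and adjusted over the 33 lists within a comparison. The test was repeated with a correlation estimated per list and with fry, which tests whether a list moves one way without comparing it with other genes. Members past 0.05 were counted with adjustment over all probe sets and adjusted over the list alone. The genes of each chromosome were tested the same way, and the median deviation of each chromosome was taken per array over genes above the median of all probe sets.

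The genes named in the text follow a rule fixed before the data were examined. In each comparison these are the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05, the higher group's mean above the median of all probe sets and no overlap between the arrays of the groups, leaving out clone names. Where fewer than 5 passed in a direction, the 5 smallest p-values are given as values. Up to 4 members of each list with the smallest p were added, as were 16 genes of stem cell biology and ageing named in every comparison.

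The limma step was tested on simulated data before use, with 200 of 28944 probe sets changed in each of 20 draws. Long against short culture of young donors recovered 23.6% of changes of log2 0.5, 94.4% of log2 1 and 100% of log2 2, with 5.01% false calls. Serial transplant against young donors in long culture recovered 12.1%, 88.4% and 100%, with 5.53% false calls, and serial transplant against short culture 14.6%, 90.2% and 99.6%, with 5.46%. Overlap between comparisons that share arrays was set beside 100 simulations of unchanged groups and beside the overlap of independent lists.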

Results

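Gene expression was measured on 8 arrays that each held total RNA of mouse spermatogonial stem cells, the self-renewing germ cells of the testis, taken from culture. The arrays fell into 3 groups. In 3 arrays the cells came from donors of 8 days and had been cultured for 7 to 10 weeks (young donor, short culture). In 3 further arrays the donors were also 8 days old and culture had lasted 14 to 18 months (young donor, long culture). The remaining 2 arrays held cells of a serial-transplant line, in which stem cells are passed from testis to testis. Their labels give a donor age of 1500 days, and culture again lasted 14 to 18 months (serial transplant, long culture). Donor age and serial transplantation came together in that group, so no comparison separates them. Whether the 1500 days are the age of a single animal or of the line over its transplants was not examined here. The study asked which genes differ between these cells. Values are log2 signals for 28944 probe sets, with array medians between 6.90 and 6.98, and the number of arrays limits the precision of every estimate.

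The arrays separated by length of culture. On the first principal component, which held 54.6% of the variance, the short-culture arrays lay at 25.4, 52.0 and 18.9 and the 5 long-culture arrays between -29.5 and -11.7. Young short-culture replicate 2 stood apart from its group, with correlations of 0.991 and 0.990 to the other replicates where those correlated at 0.996 with each other, and it had the lowest array weight (0.329). Relative to the 8-array mean of each gene, its fibroblast genes had a median of 0.96, the highest of all arrays, and its genes of the G2 and M phases one of -0.52, the lowest. No 2 arrays held the same values.

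The comparison of long with short culture of young-donor cells asks what more than a year in vitro does to cells of the same donor age. Markers of undifferentiated spermatogonia moved both ways, 5 rising and 5 falling among 33. Bcl6b, a transcription factor induced by GDNF (glial cell line-derived neurotrophic factor, the main self-renewal signal of these cells), fell 2.01-fold (SE 0.16 log2, n = 3 and 3; limma, Benjamini-Hochberg adjusted p = 0.00500), Lhx1, also GDNF-induced, changed by -1.30 ± 0.23 log2 (adjusted p = 0.00626) and Id4, an inhibitor of differentiation found in the most primitive spermatogonia, by -0.80 ± 0.12 (adjusted p = 0.00353). Ret (0.75) and Nanos3 (0.79) rose, and Gfra1, Etv5 and Zbtb16 did not pass. Kit, the receptor that marks differentiating spermatogonia, rose by 1.41 ± 0.16 (adjusted p = 0.00123), from 8.90 ± 0.38 (SD) to 10.31 ± 0.05. Large falls were those of Tex19.1, a germ cell gene that restrains retrotransposons (-3.51 ± 0.22, adjusted p = 2.63e-05), and of the granzyme genes Gzmc (-5.77 ± 0.27) and Gzmd (-5.40 ± 0.26), which encode proteases of cytotoxic lymphocytes. The long-culture means of Gzmc (4.21) and Gzmd (4.04) lie below the lower quartile of every array (5.32 to 5.52), in the range of background, so their falls are lower bounds and their order is open.

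**Figure D1:**
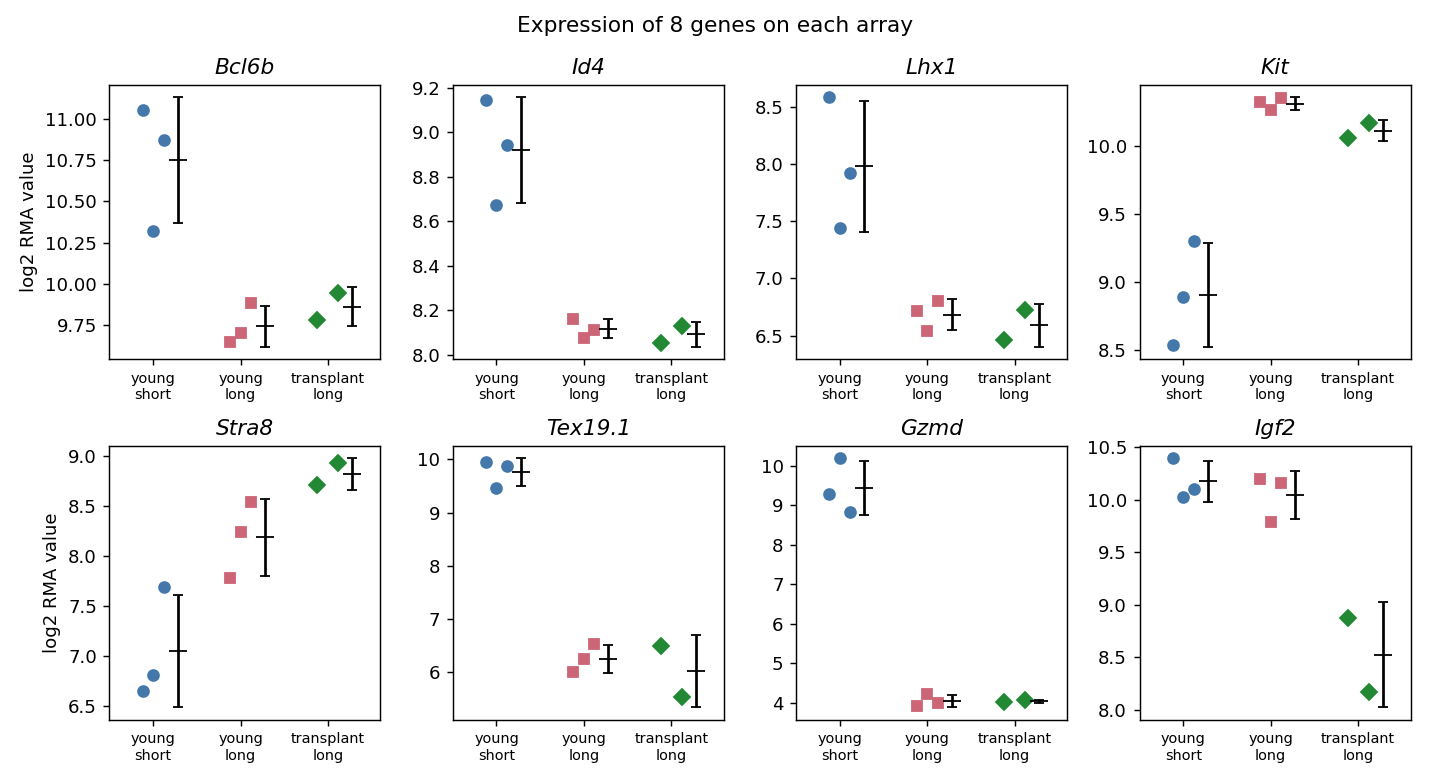
Log2 RMA values (y axis) of 8 genes on each array, grouped by donor and culture (x axis); points are arrays, dashes and bars are group means and SD. Gzmd lay between 8.84 and 10.20 on the short-culture arrays and at most at 4.22 on the long-culture ones, and Igf2 was lower on both serial-transplant arrays (8.88 and 8.17) than on any other.

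Of 28944 probe sets, 3260 passed an adjusted p of 0.05 in limma, 1573 higher and 1687 lower after long culture, which came to 1217 higher and 1334 lower among 19939 genes. With an added requirement of a log2 change of at least 1, 88 were higher and 308 lower. Centring each array on its median moved the higher share from 48.3% to 59.7% (1970 higher, 1331 lower), so the balance of directions depends on the scaling. The count was 1383 without young long-culture replicate 1 and 1085 without replicate 3. Of 109 genes named in this comparison that passed, 28 no longer did without young long-culture replicate 3, 24 without replicate 1, 14 without replicate 2, and 9, 12 and 6 without young short-culture replicates 1, 2 and 3.

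Besides Kit, the genes with the largest rises were Nrk (1.93), Cd24a (1.91), A2m (1.74), Flt3 (1.74), Csta2 (1.59), Alox12e (1.59), Zdhhc2 (1.58), Satb1 (1.57), Lgals2 (1.51), Muc1 (2.82-fold) and Tlcd4 (1.45), all with limma adjusted p between 0.000368 and 0.00684. Flt3 is a receptor tyrosine kinase related to Kit, Cd24a a surface glycoprotein and Satb1 a chromatin organiser. The other large falls were those of Srgn (-2.90), Cpa3 (-2.79), Npy1r (-2.51), Prl2c5 (-2.47), Cyp11a1 (-2.35), Laptm5 (-2.29), Saa3 (-2.14), Gzme (-2.14) and Aldh1a1 (-2.12). Srgn encodes the granule proteoglycan of blood cells, Cpa3 a mast cell protease and Cyp11a1 the enzyme that starts steroid synthesis. Gzmc, Gzmd and Gzme are close paralogs whose probes can share targets, so their separate values are uncertain. Srgn, Cpa3, Cyp11a1, Laptm5 and Gzme in long culture and Csta2 in short culture had means below 5.52, the highest lower quartile of an array, so their changes are lower bounds too. Among the genes fixed in advance, Ret, the GDNF receptor subunit, rose by 0.75 ± 0.19, while Mapk10, the neuronal JNK kinase, changed by -1.62 ± 0.26, Col1a1 by -0.70 ± 0.15 and Thy1 by -0.47 ± 0.12. Ret no longer passed without young long-culture replicate 1 (adjusted p = 0.114), replicate 3 (0.105) or young short-culture replicate 2 (0.0540), Col1a1 without young long-culture replicate 1 (0.0604) or 3 (0.0501), and Thy1 without any of 5 arrays (0.0601 to 0.103). Gfra1 (0.18), Etv5 (0.03), Zbtb16 (0.27), Ddx4 (-0.35), Cdkn2a (0.25) and Igf2 (-0.12) did not pass the test.

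Germ cell lists moved in parts, beside a fall of the fibroblast list (median -0.74) in the same comparison. Of 33 measured markers of undifferentiated spermatogonia, 5 rose and 5 fell (8 and 6 adjusted over the list alone), with Nanos3 at 0.79 beside the falls of Lhx1, Bcl6b and Id4, and the list as a whole did not pass camera (median 0.04, adjusted p = 0.256). Of 23 genes of GDNF and FGF signalling, 1 rose and 6 fell (1 and 7 adjusted over the list alone), among them Dusp4 at -1.10 and Cxcl12 at -0.58. That list did not pass camera (adjusted p = 0.105, and adjusted p = 0.659 with an estimated correlation) but did at the preset correlation without young short-culture replicate 2 (adjusted p = 0.00185). Of 15 markers of differentiating spermatogonia, 7 rose and 1 fell (8 and 1 adjusted over the list alone), with Kit, Nanos3, Rhox13 (0.69) and Sohlh2 (0.62) higher, and the list rose in camera (median 0.38, adjusted p = 0.000357, and adjusted p = 0.507 with an estimated correlation). The 1 that fell was Sohlh1 (-0.49), named after its value was seen. Nanos3 is a member of both the undifferentiated and the differentiating list, so its rise is counted in each. Of 25 meiotic genes, 7 rose and 1 fell (12 and 2 adjusted over the list alone), including Meioc (1.11) against Tex12 (-1.38, both means below the median of all probe sets), and the list rose (median 0.28, adjusted p = 1.29e-05, and adjusted p = 0.507 with an estimated correlation). Of 26 core germ cell genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone), with Dazl at 0.46 and Tdrd9 at -2.10. Its median was 0.20 and its mean -0.06, and camera placed it higher (adjusted p = 0.0264, and adjusted p = 0.659 with an estimated correlation), a call that was lost without young long-culture replicate 2 (adjusted p = 0.120), without replicate 3 (0.0543) or without young short-culture replicate 2 (0.172). Of 22 pluripotency genes 3 rose (3 adjusted over the list alone), namely Fbxo15 (1.03), Tfcp2l1 (0.64) and Esrrb (0.54), and none of 21 spermatid genes passed by either adjustment. The meiotic risers include Meiob (0.87), whose means of 4.42 and 3.55 lie below the lower quartile of every array, so its rise cannot be told from background. Neither the pluripotency nor the spermatid list passed camera (adjusted p = 0.196 and 0.679). Counts of members depended on single arrays: without young short-culture replicate 2 there were 3 risers among the meiotic and 2 among the core germ cell genes. Without young long-culture replicate 3 there were 2 and 1, with 4 among the differentiating and 1 among the undifferentiated markers, and without replicate 1 these 4 counts were 4, 1, 5 and 1. Without young long-culture replicate 2 the meiotic and core risers numbered 2 and 2, and without young short-culture replicate 1, 4 and 1.

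Cell-division genes were higher after long culture. All 38 measured genes of the G2 and M phases had a positive change, 19 of them past the test (35 adjusted over the list alone), including Nusap1 (0.85), Ttk (0.79), Ccnb2 (0.74) and Cdca8 (0.68). The list rose (median 0.47, adjusted p = 2.49e-17, and adjusted p = 0.507 with an estimated correlation), and without young short-culture replicate 2 its median was 0.35 with 13 genes past the test. Without young long-culture replicate 1 or 3, 5 passed. Of 46 DNA repair genes 13 rose and none fell (14 and 0 adjusted over the list alone), led by Brca2, Wrn, Atr and Prkdc (0.56 to 0.78; list adjusted p = 7.97e-08, and adjusted p = 0.507 with an estimated correlation). Of 40 replication genes 7 rose (10 adjusted over the list alone), such as Rpa2 (0.55) and Rfc5 (0.64; list adjusted p = 4.20e-06, and adjusted p = 0.597 with an estimated correlation). Without young short-culture replicate 2 the risers numbered 8 among the repair genes and 1 among the replication genes, and without young long-culture replicate 1 or 3 they numbered 4 and 1. Without replicate 2 they numbered 7 and 4. Of 29 genes of chromatin silencing 5 rose (7 adjusted over the list alone), among them the Polycomb genes Ezh2 (0.62) and Suz12 (0.51; 0 without young long-culture replicate 1 or 3; list adjusted p = 9.65e-05, and adjusted p = 0.597 with an estimated correlation). Of 20 telomere genes only Pot1a rose (0.49; 1 adjusted over the list alone). That list was higher in camera (adjusted p = 0.0161, and adjusted p = 0.597 with an estimated correlation), which was lost without young short-culture replicate 2 (adjusted p = 0.308).

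Genes of oxidative phosphorylation and cholesterol synthesis were higher as lists, beside the fall of the fibroblast list (median -0.74), and glycolysis genes did not pass as a list. Of 68 genes of oxidative phosphorylation 9 rose and none fell (9 and 0 adjusted over the list alone), led by Ndufb9 at 0.81. There was 1 riser without young long-culture replicate 1 or 3 and there were 4 without young short-culture replicate 1. The list rose (median 0.15, or 0.09 without young short-culture replicate 3, adjusted p = 3.16e-05, and adjusted p = 0.597 with an estimated correlation). Of 21 glycolysis genes 4 fell and none rose (4 fell and 5 rose adjusted over the list alone), namely Eno2 (-0.77), Pgk1 (-0.57), Tpi1 (-0.43) and Aldoa (-0.36). These counts depended on single arrays. With replicate 2 of either young group left out, 1 rose and 2 fell. With young short-culture replicate 3 left out, 5 rose and 3 fell, and with any other of the 6 arrays left out, none rose and 2 fell. The list did not pass camera (adjusted p = 0.805), and its median of -0.00 and mean of 0.08 differ in sign. Of 20 cholesterol synthesis genes Sqle rose (0.84) and Ebp fell (-0.81; 2 and 1 adjusted over the list alone), with a list median of 0.29 (adjusted p = 0.00413, and adjusted p = 0.597 with an estimated correlation). Without young short-culture replicate 2 the cholesterol call was lost (median 0.16, adjusted p = 0.0839), as was that of 15 heat shock genes, of which 3 rose and 1 fell by either adjustment (adjusted p = 0.0179, 0.0528 without that array, and adjusted p = 0.507 with an estimated correlation).

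Apart from the heat shock genes, lists of stress and growth arrest did not rise as groups. Of 25 p53 target genes 2 rose and 6 fell (4 and 8 adjusted over the list alone), with Zmat3 at -1.03, Phlda3 at -0.78, Plk2 at -0.77 and Ccng1 at -0.73. Of 26 senescence-associated genes 3 rose and 4 fell (3 and 7 adjusted over the list alone), with Mmp3 (-1.49) and Ccl2 (-1.40), secreted products of senescent cells and fibroblasts, lower and Hmgb2 (0.85) higher. Of 35 genes of oxidative stress defence 2 rose and 11 fell (3 and 12 adjusted over the list alone), with Mgst1 at -1.53 and Gsta4 at -1.16, and 5, 5 and 4 fell without young long-culture replicates 1, 2 and 3 and 5 without young short-culture replicate 1. Of 25 genes of JNK and AP-1 signalling 2 rose and 3 fell (4 and 5 adjusted over the list alone), with Fosl2 at -0.66 and Map3k12 at 0.52. In this last list the median (0.02) and mean (-0.06) differ in sign. Of 22 genes of the Bcl2 and caspase families 1 rose and 5 fell (1 and 6 adjusted over the list alone), with Casp8 at -1.18, Bak1 at -0.78, Bcl2 at -0.43 and Bik at 0.59. The fallers numbered 2 without young short-culture replicate 2 or young long-culture replicate 1, and 1 without young long-culture replicate 3. Of 26 genes of the unfolded protein response only Xbp1 fell (-0.37; 0 adjusted over the list alone). The senescence list had a median of -0.19, but -0.04 without young short-culture replicate 2. None of these 6 lists passed camera (adjusted p between 0.0695 for the Bcl2 and caspase list and 0.944 for JNK and AP-1 signalling), although the Bcl2 and caspase list did without young short-culture replicate 2 (adjusted p = 0.0326). Fry, with all arrays, called the Bcl2 and caspase list lower (adjusted p = 0.00626) and none of the others.

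Fibroblast, interferon-response, macrophage and Leydig cell lists were lower after long culture at the preset correlation but not at an estimated one. Of 31 fibroblast genes 18 fell and none rose (25 and 1 adjusted over the list alone), including Acta2 (-1.24), Cald1 (-1.06), Col1a2 (-1.04) and Mmp2 (-1.02). The list fell (median -0.74, adjusted p = 2.32e-11, and adjusted p = 0.507 with an estimated correlation), and its median was -0.64 without young short-culture replicate 2. Without young long-culture replicates 1, 2 and 3 in turn, 11, 11 and 9 fibroblast genes fell. Of 26 interferon-response genes 10 fell and 1 rose (15 and 2 adjusted over the list alone), with Ifit3 at -1.79, Ifit2 at -1.35, Tap1 at -0.87 and Ifih1 at 0.54, and the fallers numbered 5, 5 and 3 without young long-culture replicates 1, 2 and 3. Of 16 macrophage genes 4 fell (5 adjusted over the list alone), namely Laptm5, Fcer1g (-1.69), Ptprc (-1.42) and Tyrobp (-0.86), and of 9 Leydig cell genes 3 fell by either adjustment, namely Cyp11a1, Star and Nr5a1 (-0.51). These 3 lists fell in camera (adjusted p = 3.16e-05, 0.000357 and 0.0154), each with adjusted p = 0.507 with an estimated correlation. Only 5 of the 16 macrophage and 3 of the 9 Leydig genes had a short-culture mean above the median of all probe sets, and Tyrobp and Nr5a1 were not among them. Leydig fallers numbered 1 without young long-culture replicate 1 or 3. Of 17 Sertoli cell genes 2 rose, Aard (1.25) and Wt1 (0.90), and 3 fell, among them Kitl (-1.52; 2 and 5 adjusted over the list alone), and none of 14 endothelial genes passed by either adjustment. Neither list passed camera (adjusted p = 0.202 and 0.542).

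Imprinted genes changed one by one. Of 20 paternally expressed genes 4 rose, Peg10 (1.39), Nnat (1.23), Sgce (1.12) and Ndn (0.97), and 3 fell (4 and 4 adjusted over the list alone). The median of the list (-0.06) and its mean (0.02) differ in sign, and it did not pass camera (adjusted p = 0.800). Of 20 maternally expressed genes 2 rose and 3 fell (3 and 5 adjusted over the list alone), with Gatm at 1.11 and Dcn, which the fibroblast list also holds, at -1.16 (list adjusted p = 0.896). Of 18 DNA methylation genes Gadd45b (-0.44) and Dnmt3l (-0.51, both means below the median of all probe sets) fell (3 adjusted over the list alone; list adjusted p = 0.653, with a median of 0.04 and a mean of -0.01). Of 25 genes of integrins and niche adhesion 5 rose and 3 fell (7 and 5 adjusted over the list alone), with Cd24a, Itga9 (0.68) and Lama1 (0.53) higher (list adjusted p = 0.193). Of 8 Y-linked genes Eif2s3y (0.63) and Zfy1 (0.44) rose (2 adjusted over the list alone), and the list rose (median 0.28, adjusted p = 0.00508, and adjusted p = 0.507 with an estimated correlation). The Y-linked median was 0.16 and 1 gene passed without young short-culture replicate 2. None passed without young long-culture replicate 1 or 3. In all, camera called 16 of the 33 lists, 12 higher and 4 lower, and none with an estimated correlation. The balance depended on the scaling: after quantile normalization 8 were higher and 8 lower, with the lists of GDNF and FGF signalling (adjusted p = 0.0176), oxidative stress defence (0.0174), the Bcl2 and caspase families (0.0190) and the unfolded protein response (0.0471) newly lower. Without dim probe sets 7 were higher and 5 lower, and without young short-culture replicate 2 these counts were 8 and 6.

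**Figure D2:**
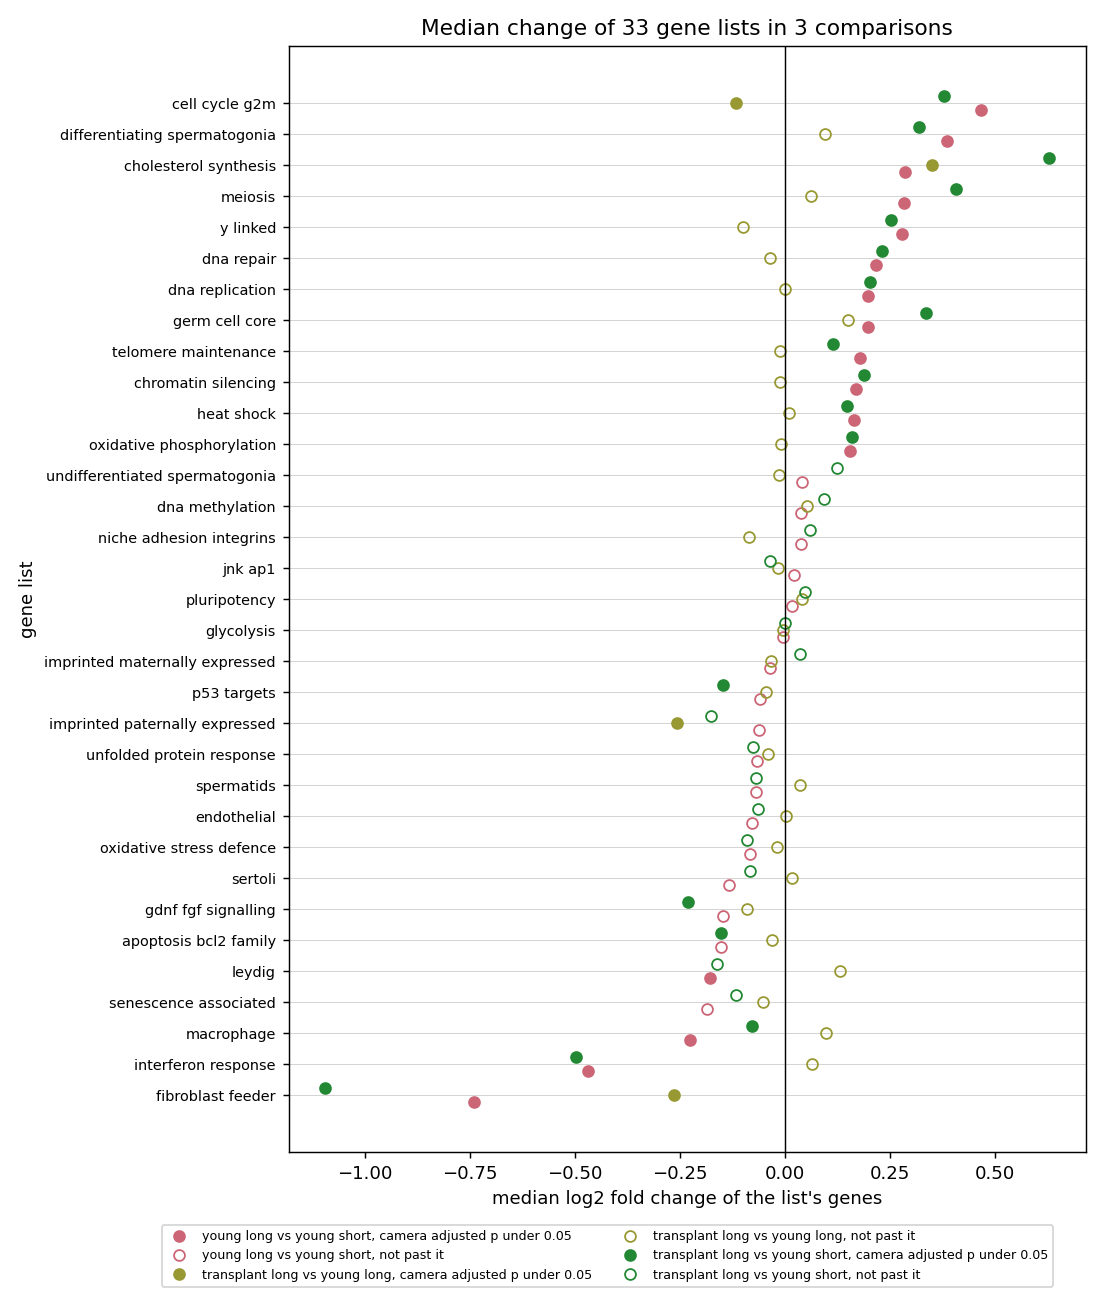
Median log2 fold change (x axis) of the measured genes of each of 33 lists (y axis) in the 3 comparisons; filled points passed a camera adjusted p of 0.05 at the preset correlation. Fibroblast genes lay at -0.74 and -1.09 in the comparisons with short culture, cell-cycle genes at 0.47 and 0.38.

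The comparison of serial-transplant with young-donor cells after long culture asks what an old, serially transplanted germ line adds at the same culture age. No gene passed the adjusted test, so the following are values only. The smallest p-values belonged to lower signals in the serial-transplant arrays. Igf2, the paternally expressed growth factor, differed by -1.52 ± 0.20 log2 (SE, n = 2 and 3), Zic1, a zinc finger transcription factor, by -2.66 ± 0.35, the integrin gene Itga1 by -1.06 ± 0.14, the glutamate receptor gene Grin2a by -0.84 ± 0.11 and the retinaldehyde dehydrogenase gene Aldh1a3 by -1.06 ± 0.14 (limma, Benjamini-Hochberg adjusted p = 0.0627 for each). In the other direction the smallest p-values were those of Clstn1 (0.81, adjusted p = 0.114), Krt8 (0.75), Mcu (0.66), Olfr1230 (0.56) and Mlkl (0.71), with adjusted p up to 0.304 and with Grin2a, Olfr1230 and Mlkl below the median of all probe sets in both groups.

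In limma, 0 of 28944 probe sets passed, and 2079 had an unadjusted p under 0.05 against 1447.2 expected by chance. In the simulation with 200 changed probe sets, 88.4% of changes of log2 1 and 12.1% of log2 0.5 were found at these group sizes. The adjusted test is stricter where fewer probe sets change, so these shares do not carry over to a comparison with 0 calls. Zic1, Igf2, Itga1 and Aldh1a3 each differed by more than log2 1 here and still missed the threshold. Array weights gave 22 calls (2 higher, 20 lower), a fit on the arrays of these 2 groups alone gave 15 (1 higher, 14 lower) and the mean of all probe sets per gene gave 6 genes, all lower. Of the stem cell genes named in advance, Bcl6b (0.12 ± 0.18), Id4 (-0.02 ± 0.13), Lhx1 (-0.09 ± 0.25), Gfra1 (-0.14 ± 0.15), Ret (-0.35 ± 0.21), Etv5 (0.09 ± 0.18), Zbtb16 (-0.10 ± 0.13), Kit (-0.20 ± 0.18) and Thy1 (0.14 ± 0.13) had adjusted p between 0.789 and 0.989. Cdkn2a differed by -0.01 ± 0.11, Ddx4 by 0.56 ± 0.23, Mapk10 by 0.66 ± 0.29 and Col1a1 by -0.14 ± 0.16, and none of these passed either.

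Camera called 4 of the 33 lists. Cholesterol synthesis genes were higher in serial-transplant cells, 19 of 20 with a positive change (median 0.35, or 0.22 without serial-transplant replicate 2, adjusted p = 4.28e-09, and adjusted p = 0.833 with an estimated correlation), with Mvd at 1.02 ± 0.28 and Msmo1 at 0.53 ± 0.20, though no single member passed by either adjustment. Paternally expressed imprinted genes were lower, 16 of 20 with a negative change (median -0.26, or -0.11 without serial-transplant replicate 2, adjusted p = 1.12e-06, and adjusted p = 0.244 with an estimated correlation). No member passed over all probe sets and 7 were lower when adjusted over the list alone, with Igf2, Nnat (-0.86 ± 0.19), Peg10 (-0.71 ± 0.17) and Airn (-0.63 ± 0.15, below the median of all probe sets in both groups) first by p. Fibroblast genes were lower (median -0.26, adjusted p = 1.20e-06, and adjusted p = 0.988 with an estimated correlation), but without serial-transplant replicate 2 the median was 0.01 (adjusted p = 0.907). Genes of the G2 and M phases were lower (median -0.12, adjusted p = 0.000409, and adjusted p = 0.988 with an estimated correlation), a call lost without serial-transplant replicate 1 (adjusted p = 0.536) or young long-culture replicate 1 (adjusted p = 0.162). No member of either of these 2 lists passed by either adjustment. The lowest p among undifferentiated markers was that of Eomes (-1.23 ± 0.19, adjusted p = 0.114), among p53 targets that of Pmaip1 (-1.12 ± 0.20, adjusted p = 0.245) and among pluripotency genes those of Dppa2 (0.54 ± 0.16) and Utf1 (0.72 ± 0.23). Among the lists that camera did not call, the median, mean and direction of the test did not share a sign for replication, endothelial, heat shock, telomere and unfolded protein response genes.

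The 955 measured genes of chromosome 8 were higher in serial-transplant than in young long-culture cells at the preset correlation, 784 with a positive change (median 0.16; camera adjusted p = 2.24e-16, and adjusted p = 0.507 with an estimated correlation), but the rotation test fry did not call them (adjusted p = 0.268). Those of chromosome 15 (median 0.07, adjusted p = 0.00130, and adjusted p = 0.557 with an estimated correlation) and chromosome 13 (median 0.06, adjusted p = 0.0181, and adjusted p = 0.557 with an estimated correlation) were also higher, but neither call held without young long-culture replicate 1 (adjusted p = 0.0856 and 0.587), and that of chromosome 13 was also lost without serial-transplant replicate 2 (0.369). Fry called neither (adjusted p = 0.590 and 0.694). Against short culture, chromosome 8 (median 0.16, 160 genes higher and 39 lower, adjusted p = 2.13e-08, and adjusted p = 0.413 with an estimated correlation) and chromosome 15 (median 0.13, 157 higher and 32 lower, adjusted p = 2.70e-07, and adjusted p = 0.413 with an estimated correlation) were higher in serial-transplant cells. Fry, which tests against no change and not against other genes, placed both higher (adjusted p = 0.0473 and 0.0250) and chromosomes 2, 3, 5, 10, 11 and X lower (0.0221 to 0.0473). Between long and short culture of young donors only chromosome 15 was higher (median 0.04, 143 genes higher and 43 lower, adjusted p = 0.00724, and adjusted p = 0.770 with an estimated correlation), and not without young long-culture replicate 2 (adjusted p = 0.0994) or in fry (0.0690). Over its genes above the median of all probe sets, chromosome 15 deviated by -0.15, -0.20 and -0.08 on short-culture replicates 1, 2 and 3. On young long-culture replicates 1, 2 and 3 it deviated by -0.04, 0.10 and 0.10, and on the serial-transplant arrays by 0.15 and 0.14. Between long and short culture of young donors fry placed chromosomes 2, 5, 7, 10 and 11 lower (adjusted p = 0.00609 to 0.0308). Camera, which compares with other genes, called none of these (adjusted p = 0.672 to 0.917). The median change of all probe sets was itself -0.035 in that comparison, so these fry calls are no sign of shifts particular to those chromosomes.

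**Figure D3:**
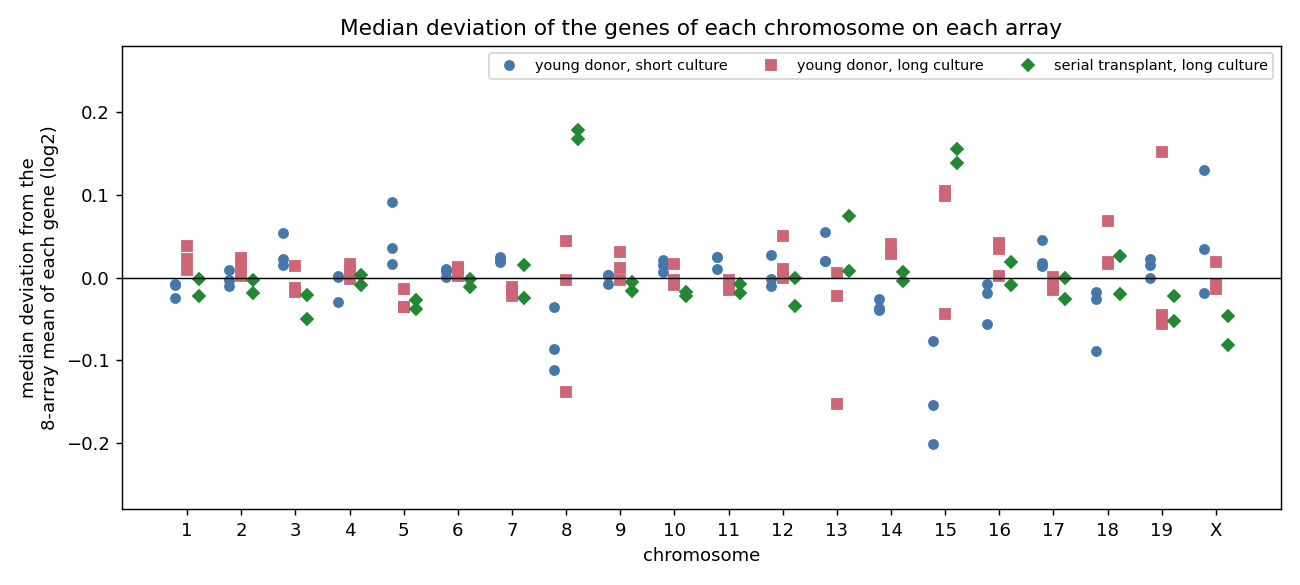
Median deviation (y axis, log2) from the 8-array mean of each gene, over the genes of each chromosome (x axis) with a mean above the median of all probe sets; each point is 1 array. Chromosome 8 stood at 0.17 and 0.18 on the serial-transplant arrays, while young long-culture replicate 1 stood at 0.15 on chromosome 19 and -0.15 on chromosome 13. Chromosome 15 stood between -0.20 and -0.08 on the short-culture arrays and at 0.15 and 0.14 on the serial-transplant ones.

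The comparison of serial-transplant, long-culture cells with young-donor, short-culture cells combines donor age, serial transplantation and culture time. Again Bcl6b (-0.89 ± 0.18, adjusted p = 0.0143), Id4 (-0.83 ± 0.13, adjusted p = 0.00570) and Lhx1 (-1.39 ± 0.25, adjusted p = 0.00815) fell and Kit rose (1.21 ± 0.18, adjusted p = 0.00411; limma, n = 2 and 3). Stra8, the retinoic acid-induced gene of meiotic entry, rose by 1.77 ± 0.28 (adjusted p = 0.00544), and Igf2 fell by 1.65 log2 (adjusted p = 0.00224). Stra8 also lay higher on the young long-culture arrays (7.78, 8.24 and 8.54) than on the short-culture ones (6.65, 6.81 and 7.69). Tex19.1 (-3.74 ± 0.25), Gzmc (-5.56 ± 0.31) and Gzmd (-5.40 ± 0.29) again fell, the granzyme genes to background (means 4.42 and 4.04), so that their falls are lower bounds. The largest rise was that of Fndc3c1 (2.31 ± 0.31, adjusted p = 0.00316), and Mvd, an enzyme of cholesterol synthesis, rose 2.83-fold (SE 0.28 log2, adjusted p = 0.00931). Without serial-transplant replicate 2 the direction of each held, but Bcl6b (adjusted p = 0.121), Id4 (0.0809), Lhx1 (0.0901), Kit (0.0814), Stra8 (0.0979), Fndc3c1 (0.0692) and Mvd (0.146) no longer passed, and without replicate 1 neither did Bcl6b (0.0937) or Lhx1 (0.0607).

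The test called 2528 probe sets, 1037 higher and 1491 lower, or 818 higher and 1189 lower among genes. With a log2 change of at least 1 the counts were 96 higher and 468 lower, and centring the arrays moved the higher share from 41.0% to 51.0%. The count fell to 66 without serial-transplant replicate 2, 1528 without serial-transplant replicate 1 and 1252 in a fit on these 2 groups alone. Of 60 genes named in this comparison that passed, 49 no longer did without serial-transplant replicate 2. Those that still passed were Gzmc, Gzmd, Tex19.1, Igf2, Zdhhc2, Adgrf5, Adam22, Srgn, Adh1, Aldh1a1 and Laptm5. With all arrays, A2m (1.95), Zdhhc2 (1.89), Dmrt2 (1.66), Lgals2 (1.66), Krt18 (1.61), Adgrf5 (1.60), Adam22 (1.53), Crybg1 (1.46) and Ropn1l (1.43) rose. Cpa3 (-2.78), Saa3 (-2.72), Prl2c5 (-2.69), Srgn (-2.67), Npy1r (-2.67), Serpina3n (-2.64), Adh1 (-2.27), Mme (-2.27) and Aldh1a1 (-2.25) fell, as did Col1a1 (-0.84), with Cpa3 and Srgn at background in serial-transplant cells and their falls lower bounds. Gfra1 (0.04), Ret (0.40), Etv5 (0.12), Zbtb16 (0.18), Ddx4 (0.21), Cdkn2a (0.23), Mapk10 (-0.96) and Thy1 (-0.33) did not pass.

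Camera called 18 lists in this comparison, 12 higher and 6 lower, and each had adjusted p = 0.497 with an estimated correlation. Without serial-transplant replicate 2 the only members of these lists that passed were 2 core germ cell and 2 macrophage genes, all lower, so the following member counts rest on that array. Of 31 fibroblast genes 24 fell and none rose (27 and 0 adjusted over the list alone), with Pdgfra at -2.01, Cald1 at -1.33 and Col1a2 at -1.26 (median -1.09, list adjusted p = 2.28e-18). Of 20 cholesterol synthesis genes 9 rose and 1 fell (17 and 1 adjusted over the list alone), with Mvd, Sqle (1.17), Idi1 (1.02) and Msmo1 (1.02) higher (median 0.63, list adjusted p = 2.25e-09). Of 15 differentiation markers 6 rose (7 adjusted over the list alone), including Stra8, Kit, Nanos3 (0.86) and Tex101 (0.82; list adjusted p = 6.71e-06), and of 25 meiotic genes 6 rose (14 rose and 2 fell adjusted over the list alone), including Syce2 (0.94), Tex15 (0.68), Rec8 (0.55) and Sycp3 (0.51; list adjusted p = 6.71e-06). Of 38 genes of the G2 and M phases 5 rose (10 adjusted over the list alone), including Ccnb2 (0.63) and Cdca8 (0.56; list adjusted p = 3.04e-10). Of 26 core germ cell genes 3 rose and 2 fell (11 and 3 adjusted over the list alone; list higher at adjusted p = 0.000616). Without young short-culture replicate 2 the risers numbered 1 among the genes of the G2 and M phases, whose median was then 0.23 in place of 0.38, and 2 among the meiotic genes. Meiotic risers numbered 1 without young short-culture replicate 1 and 2 without serial-transplant replicate 1. All of these calls had adjusted p = 0.497 with an estimated correlation.

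Among 26 interferon-response genes 7 fell and 1 rose (11 and 1 adjusted over the list alone), with Ifit3 at -1.80 and B2m at -1.25 (list adjusted p = 0.000344), and among 16 macrophage genes 5 fell by either adjustment, with Laptm5 at -2.18 and Mrc1 at -1.44 (list adjusted p = 0.00224). Of 23 genes of GDNF and FGF signalling 5 fell (7 adjusted over the list alone), with Cxcl12 at -0.86 and Fgfr2 at -0.49, the latter below the median of all probe sets in both groups (list adjusted p = 0.00988, and 0.0914 without young short-culture replicate 1). Of 25 p53 targets 2 rose and 8 fell (3 and 9 adjusted over the list alone), with Eda2r at -1.46 and Pmaip1 at -0.97 (list adjusted p = 0.0492, and 0.123 without young short-culture replicate 1 or 0.0628 without serial-transplant replicate 1). Of 22 genes of the Bcl2 and caspase families 6 fell (1 rose and 8 fell adjusted over the list alone), with Casp8 at -1.22 (list adjusted p = 0.0176). These falls stand beside that of the fibroblast list (median -1.09). All 5 of these lists had adjusted p = 0.497 with an estimated correlation. The other 7 called lists were all higher: DNA repair, replication, chromatin silencing, oxidative phosphorylation, telomere, heat shock and Y-linked genes, with Wrn at 0.65, Prim1 at 0.61, Ndufb9 at 0.84 and Terf2 at 0.49 among the genes that rose, and again adjusted p = 0.497 with an estimated correlation. Without young short-culture replicate 2, chromatin silencing (adjusted p = 0.0537), telomere (0.239), heat shock (0.0679) and Y-linked (0.314) genes lost their call, and without serial-transplant replicate 2 so did oxidative phosphorylation (0.0523), heat shock (0.114) and Y-linked (0.124) genes. Paternally expressed imprinted genes, of which 2 rose and 6 fell (3 and 6 adjusted over the list alone), with Igf2, Impact (-1.50), Dlk1 (-1.41) and Airn (-0.93) lower, missed the threshold (adjusted p = 0.0538). The median, mean and direction of the test did not share a sign for glycolysis, maternally expressed imprinted and niche adhesion genes, none of which camera called.

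Calls of the comparisons against short culture overlapped. Of 2551 genes called after long culture of young-donor cells and 2007 called in serial-transplant cells, 538 were higher and 887 lower in both, and 0 had opposite directions; independent lists of these sizes would share 49.9 and 79.5. Both comparisons use the same 3 short-culture arrays, which correlates their changes even where neither comparison has an effect, and with 3 arrays these could not be split into 2 parts of at least 2. In 100 simulations of unchanged groups a mean of 0 genes was called in both. With no effect in any group hardly any call can arise in either comparison, so this count gives no baseline for the shared calls. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.860 against 0.446 in the simulations, and their covariance was 0.0984 against 0.00802. Part of the excess may come from the shared arrays.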

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

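Centring the arrays was tried on the gene lists only after the data had been seen; the other alternatives were planned. No probe set called in the reported tests changed sign under any alternative that tested it. Array weights gave 5079 calls for long against short culture of young donors and 22 for serial transplant against young donors in long culture. Fits on the 2 groups compared gave 15 calls for the latter and 1252 for serial transplant against short culture. A log2 change of at least 1 left 396 and 564 calls in the comparisons with short culture and 252 genes in their overlap, since it adds a condition. With the replicate block the counts were 2754, 4 and 2468. After removal of group means, arrays with the same replicate number correlated at 0.0812, 0.176 and 0.102 between long and short culture of young donors. Those with different numbers ran from -0.281 to 0.251 there. Between the long-culture groups the same numbers gave -0.0494 and -0.133, but with 2 serial-transplant arrays the values left after that removal mirror each other. So few values cannot tell whether the numbers pair the arrays. The mean of all probe sets of a gene gave 6 genes between the long-culture groups. The cause of these shifts was not tested.

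With an estimated inter-gene correlation 0 lists were called in each comparison, and with fry 4, 0 and 2, in place of 16, 4 and 18. Between long and short culture of young donors fry called the differentiating list higher and the Leydig, macrophage, and Bcl2 and caspase lists lower. The last of these was not called by camera there (adjusted p = 0.0695, against 0.00626 in fry). In serial-transplant cells against short culture fry called the differentiating list higher (adjusted p = 0.0482) and the Bcl2 and caspase list lower (0.00367). Quantile normalization gave 8 lists higher and 8 lower between long and short culture of young donors, in place of 12 and 4. Leaving out dim probe sets gave 2 chromosome shifts between long and short culture of young donors and 4 between serial transplant and short culture. Under quantile normalization, or without dim probe sets, the core germ cell list lost its call between long and short culture (adjusted p = 0.160 and 0.137), as did cholesterol synthesis (0.0538 and 0.0904), heat shock (0.107 and 0.161) and telomere genes (0.109 and 0.171). Over all alternatives, 1071 list results kept their side of the threshold, 106 lost a call, 34 gained one and 1 called list reversed. For chromosomes, tried without dim probe sets and without each array, these counts were 388, 4, 7 and 0. A reversal was counted here only where the reported test had made a call. A changed direction of an uncalled list or chromosome is therefore among the results that kept their side. With an estimated correlation 0 of the 1, 3 and 2 chromosome shifts held. Among the genes named in the comparisons the 4 counts were 2460, 186, 22 and 3. For a gene called in neither fit, a changed sign counted as a reversal only if the value moved by more than its standard error.

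Leaving out 1 array at a time uses fewer arrays, and where 1 serial-transplant array is left it is assumed to vary like the other groups. Calls ranged from 1085 (without young long-culture replicate 3) to 3195 for long against short culture, with 1383 without replicate 1. They ranged from 0 to 0 between the long-culture groups. For serial transplant against short culture they ranged from 66 (without serial-transplant replicate 2) to 2817, with 1528 without replicate 1. Called lists ranged from 14 to 18, 3 to 5 and 14 to 20, and chromosome shifts from 0 (without young long-culture replicate 2) to 2 (without young short-culture replicate 1), 1 (without young long-culture replicate 1) to 4, and 2 to 2. The fibroblast list between the long-culture groups ranged from a median of -0.53 without serial-transplant replicate 1 to 0.0072 without replicate 2, where it reversed. Among genes that did not pass the test, Etv5 ranged from -0.18 (without young short-culture replicate 2) to 0.18 (without replicate 1) for long against short culture and from -0.091 to 0.27, without the same arrays, for serial transplant against short culture. Col1a1 ranged from -0.43 (without serial-transplant replicate 1) to 0.15 (without replicate 2) between the long-culture groups. RMA gives no detection call, so calls among probe sets below the median of 6.94 may rest on background; without dim probe sets 2912, 0 and 2391 were called.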

Other observations

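Of the tests in this part, only that of the general leukocyte list was chosen before its result was seen; the others were chosen after the result was seen. For the 3260 calls between long and short culture of young donors, the 10 splits of 6 arrays are too few for a share under 0.05; the real split gave 3260, the highest other 0, so 1 of 10 gave as many.

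Granzyme and other leukocyte genes were lower in both long-cultured groups. Without young short-culture replicate 2, where they were highest (Gzmc at 10.83 against 9.59 and 9.54), the median change of 8 of them was -2.01. Among these, Gzmc, Gzmd, Gzme, Srgn and Laptm5 had been named for large falls with no overlap between arrays. Such a choice favours falls that outlast the loss of any array. The median therefore shows only that these 8 genes were not raised on that array alone, and cannot decide this for leukocyte genes at large. A list of 26 general leukocyte genes, 25 of them measured, had a median change of -0.45 after long culture of young donors, 23 genes lower and 13 past the test, with Bin2 higher (0.76). Of its genes Lsp1 and Arhgdib went from 9.79 and 9.58 to 8.81 and 8.36, and 10 of the 25 were above the median of all probe sets in short culture, while Spi1 (-0.01) and Ikzf1 (-0.09) did not pass. Leukocytes in the short cultures may be a source of this signal as a hypothesis, though regulation in the cultured cells, paralogous granzyme probes and any sorting of the cells were not tested.

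Chromosome 8 genes were higher in serial-transplant than in young-donor cells after long culture, in camera at the preset correlation. None of the 955 genes passed singly, and the chromosome was not called at an estimated correlation (camera adjusted p = 0.507) or by fry (0.268). Of its 616 genes above the median level, 87.7% exceeded the median change, so the shift was spread over many genes. This share restates the 784 of 955 positive changes and is no separate test. Without young long-culture replicate 1 the median of the chromosome was 0.13, which argues against that array as the only reason. Each of 5 segments in map order had a median of at least 0.18, against at most 0.132 in segments of any other chromosome, that one on chromosome 15. An extra copy of the chromosome in part of the cells may therefore be present as a hypothesis; DNA was not analysed here. Donor age and serial transplantation stay open and untested.

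The cell-cycle list rose (19 of 38 genes past the test) and the fibroblast list fell (18 of 31) after long culture of young-donor cells. Both calls were made at the preset correlation and lost at an estimated one (camera adjusted p = 0.507 for each). Fewer fibroblasts would raise germ cell genes alike. The cell-cycle median exceeded that of core germ cell genes by 0.27, and the upper quartile of the latter was 0.39 against a cell-cycle median of 0.47. Taken per array, however, the difference overlapped between long culture (-0.025 in replicate 2) and short culture (-0.022 in replicate 1), and core germ cell genes moved both ways, so these values cannot decide whether fewer fibroblasts may be the whole reason. Without young short-culture replicate 2 the cell-cycle median was 0.35 in place of 0.47 and the fibroblast median -0.64 in place of -0.74, so that array did not carry the difference alone. Of the 31 fibroblast genes 3 are in another list. A lower share of fibroblasts stays open for every other list that was higher or lower than in short culture, in either long-cultured group, such as the differentiating, meiotic, core germ cell, oxidative phosphorylation, cholesterol synthesis, p53, GDNF and FGF, and Bcl2 and caspase lists, and the length of culture itself is untested. A lower fibroblast share also stays open for the cholesterol synthesis and paternally expressed imprinted lists called between the long-culture groups. Fibroblast genes were lowest on serial-transplant replicate 2 (median deviation -0.73, against -0.20 in replicate 1).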
